A study of Arabidopsis thaliana with 12 samples.

How the data were processed

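Shoot apices of Arabidopsis thaliana were profiled by RNA sequencing in 3 genotypes, wild type (WT, accession Col-0), the mutant ap2-12 and the line rAP2-VENUS #A6, a single named line, with 4 libraries each. Per the labels' protocols, plants grew under 16 h of light and 8 h of dark and apices were taken when the main stem was 1 cm tall. Total RNA was purified with an RNeasy kit and treated with DNase, and TruSeq libraries were sequenced as single reads of 150 bp on a HiSeq3000, per the labels. The labels call the replicates independent and biological. They give no date, batch or hour of harvest.

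The deposited table holds raw read counts per gene, whole numbers in a column per library, on genome build TAIR10 per the file headers. TopHat2, SAMtools and HTSeq are named in the submitters' processing notes without versions, roles or settings. The strand setting of the counting is not given in the sources used here, so reads of overlapping antisense genes may not have been separated, and near-identical gene copies may have exchanged or lost reads. The table has 27416 gene rows and no row of unassigned reads. Its 210 chloroplast and mitochondrial rows hold 0 counts. Library totals ran from 9680133 (WT replicate 1) to 15152704 (WT replicate 2). Gene symbols came from a RefSeq table of assembly TAIR10.1, in which 26719 of the row identifiers were found and 697 were not. Because that assembly name differs from the build of the counts, it served only for names and for which genes are neighbours, and no coordinates are printed.

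Genes were kept with edgeR's filterByExpr (18807 genes), libraries were scaled by TMM, and all 12 libraries entered a single quasi-likelihood fit (glmQLFit, glmQLFTest) with genotype as the only term. Levels are given as CPM on the TMM-scaled totals. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. Standard errors (SE) of log2 fold changes are the log2 fold change divided by the square root of its F statistic. The biological coefficient of variation was 0.174. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and the data.table package (1.17.8), with Python 3 tools for drawing only. No 2 libraries of a genotype were alike within sampling noise, since the chi-square per degree of freedom between their counts was 5.16 to 46.7.

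Before the data were examined, 19 gene lists were fixed (307 members, 260 of them kept by the filter): floral identity, flowering time and inflorescence identity, miR172 targets, miR156-targeted SPL genes, shoot meristem and boundary, gibberellin, auxin, cytokinin, abscisic acid, expansins and xyloglucan remodelling, cell cycle, tapetum and pollen, carpel and ovule, photosynthesis, xylem, sample handling, salicylic acid and defence, circadian clock, and the 4 neighbours of AP2. Each was tested with camera (limma) at a preset inter-gene correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of a comparison. The rule for the genes named was fixed at the same time. It takes AP2, the 8 largest called changes in each direction against WT (5 in each direction for rAP2-VENUS vs ap2-12) among genes with a mean of at least 5 CPM, a symbol and no overlap between the groups, up to 4 members of each list with the smallest adjusted p, and the 6 genes of each opposite pattern with the smallest larger adjusted p. Every gene the rule selects is named in the report. Floral, meristem, photosynthesis and flowering list members beyond the 4 of a list (AG, AP3, CAL, CRC, LFY, SUP, HEC2, WUS, RBCS1A and TFL1 in ap2-12, and AG in rAP2-VENUS) and the genes AT3G01345, PTAC5, PTAC16, UMAMIT12, UMAMIT28, UMAMIT45 and UMAMIT47 were named after their values were seen.

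The replicate numbers come from the labels. Libraries of rAP2-VENUS and WT with the same number deviated together from their group means, with correlations across genes of 0.63, 0.23, 0.20 and 0.43 for replicates 1 to 4, so for this comparison the numbers were treated as pairing the libraries and a fit with the replicate number as a block is given where it changes a call. Because rAP2-VENUS and ap2-12 share WT as control, 20 data sets of unchanged groups were simulated for the correlation of fold changes and the 4 WT libraries were also split 2 and 2 between the comparisons.

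The steps were tested on simulated counts with the real means, dispersions and library sizes and 200 changed genes among 18807. The changed genes were drawn only from genes above a minimum mean count, so the shares recovered do not cover genes with few counts. For ap2-12 vs WT the share recovered was 49.3% at 1.5-fold, 94% at 2-fold and 97% at 4-fold, with 4 false calls among 164. For rAP2-VENUS vs WT it was 55.2%, 88.1% and 97%, with 10 false calls among 170. These simulations hold no shared deviation between libraries. Alternatives were the replicate block, median-of-ratios and upper-quartile scaling, DESeq2, limma-voom, no or a stricter low-count filter (at least 1 CPM in 4 libraries), a fit of only the 8 libraries compared, a minimum change of 2-fold, an adjusted p under 0.01, and leaving out each library. Leaving out the 3 libraries numbered 1, the same with the block, and a clock gene score as a covariate were added after seeing the data.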

Results

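The data are read counts per gene from 12 libraries of shoot apices of Arabidopsis thaliana, the growing tip of the inflorescence with its young flower buds, taken at a stem height of 1 cm. There were 4 libraries each of WT, of ap2-12, a mutant of the floral regulator APETALA2 (AP2), and of rAP2-VENUS line #A6 (rAP2-VENUS below), a line named for an AP2 construct with the yellow fluorescent protein VENUS. The labels do not say what the r stands for or whether the line keeps the normal AP2 gene. Library totals were 9680133 to 15152704 counts. The first principal component held 43.4% of the variance, with the ap2-12 libraries at 23.2 to 66.4 and the other libraries at -49.4 to -1.37. The second held 26.9% and parted libraries within each genotype, from -41.9 for WT replicate 1 to 31.4 for WT replicate 3, and from -57.2 to 10.6 in ap2-12.

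Circadian clock genes differed between replicate numbers in every genotype. The morning gene LHY was at 224 CPM in WT replicate 1 and 22.8 CPM in WT replicate 4, at 136 and 20.8 CPM in ap2-12 replicates 1 and 4, and at 94.3 and 12.7 CPM in those of rAP2-VENUS. FKF1, a light sensor that peaks late in the day, went the other way, with 0.729 and 16.3 CPM in WT, 1.45 and 25.1 CPM in ap2-12 and 4 and 68.5 CPM in rAP2-VENUS. With genotype in the model, 5548 of 18807 genes differed between replicate numbers in edgeR's quasi-likelihood test, among them all 12 clock genes on the list. No clock gene was called between genotypes by edgeR without a replicate block.

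**Figure D1:**
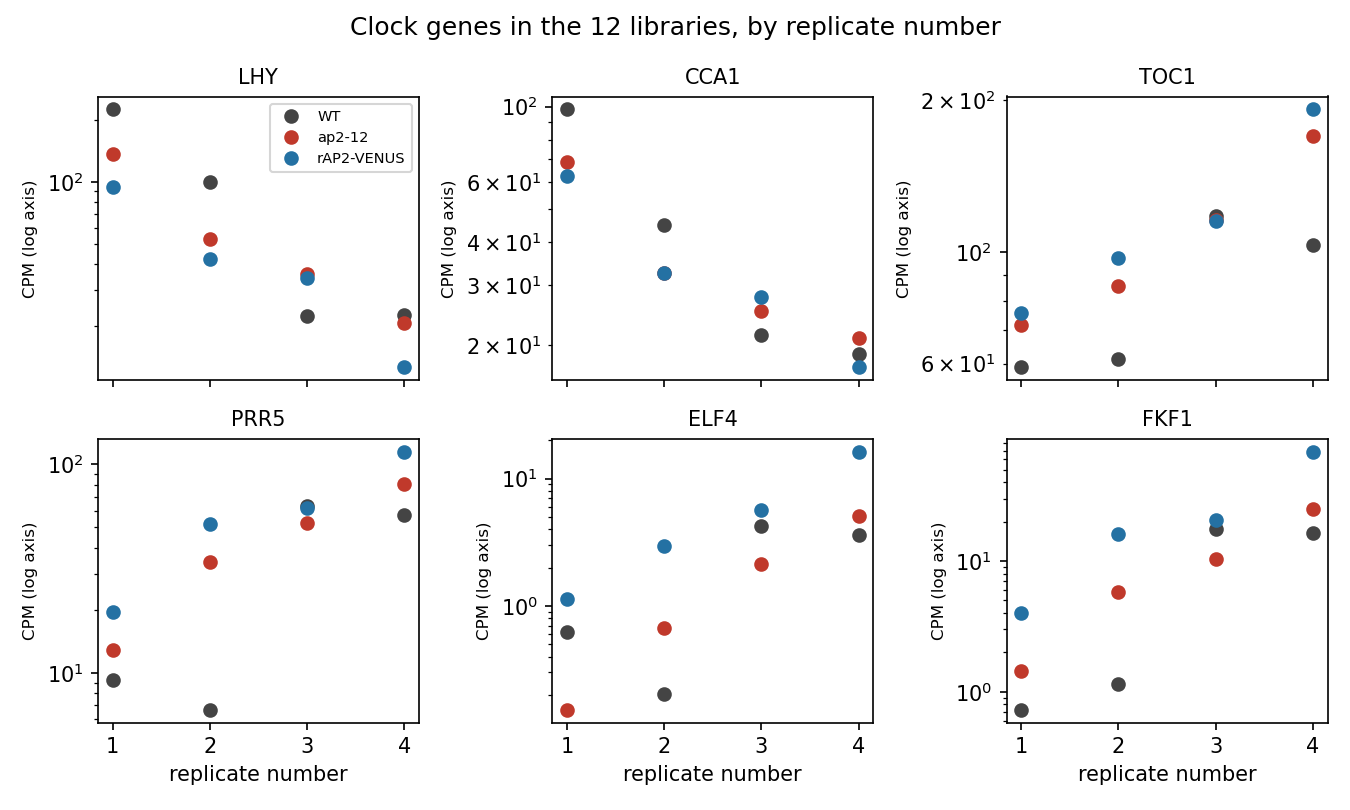
CPM (log axis) of 6 clock genes in the 12 libraries against the replicate number, with a point per library coloured by genotype. LHY falls between 12.7 and 22.8 CPM at number 4 and between 94.3 and 224 CPM at number 1 in the 3 genotypes, while FKF1 is at 16.3 to 68.5 CPM and 0.729 to 4 CPM.

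The read count of AP2 itself (AT4G36920, chromosome 4) was lower in ap2-12 and not distinguishable from WT in rAP2-VENUS. Counts per gene do not separate reads of the normal AP2 gene from those of the construct. Reads of construct sequence that differs from the genome build may not have been counted. Nor do the counts tell whether the transcripts left in ap2-12 are functional. AP2 was at 57.5 ± 23.8 CPM (SD, n = 4) in WT, 17.2 ± 2.40 in ap2-12 and 47.0 ± 7.77 in rAP2-VENUS. The log2 fold change to WT was -1.73 in ap2-12 (SE 0.23, edgeR adjusted p = 0.000302), a 3.32-fold lower level, and every ap2-12 library lay below every WT library. In rAP2-VENUS it was -0.28 (SE 0.22, adjusted p = 0.898), and 0.04 (adjusted p = 0.999) without WT replicate 1, whose 92.8 CPM stood above the 42.3 to 50.3 CPM of the other WT libraries. Of the genes next to AP2, SPT (log2 fold change 0.86) and NAPRT1 (0.32) were higher and RAP2.10 (-0.93) was lower in ap2-12, while LEJ2 (0.17, adjusted p = 0.339) was not called. In rAP2-VENUS against WT none was called, with RAP2.10 at -0.34 (adjusted p = 0.801), NAPRT1 at 0.10 (0.852), SPT at 0.10 (0.964) and LEJ2 at 0.06 (0.982). The list of neighbours as a whole did not pass (adjusted p = 0.22 in ap2-12 and 0.847 in rAP2-VENUS against WT).

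**Figure D2:**
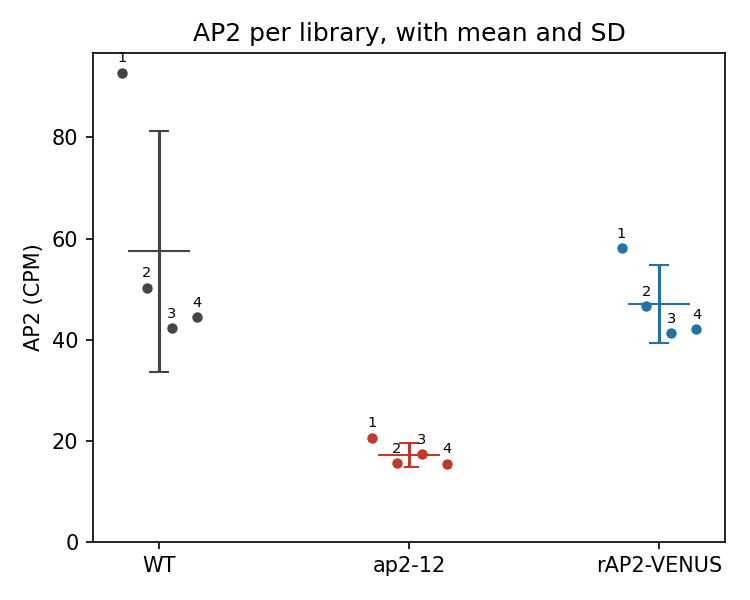
AP2 in CPM per library, with the replicate number above each point, the group mean (horizontal mark) and the SD (bar) of 4 libraries. The ap2-12 libraries sit at 15.5 to 20.6 CPM, those of rAP2-VENUS at 41.3 to 58.1 CPM and those of WT at 42.3 to 92.8 CPM.

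The comparison of ap2-12 with WT asks which apex transcripts depend on AP2. Floral regulators changed in both directions. AP1, which specifies floral meristems and sepals, fell by 1.13 on the log2 scale (SE 0.07, adjusted p = 6e-07), from 174 to 79.3 CPM. CAL fell by 1.04, LFY by 0.60, the petal and stamen gene AP3 by 1.07 and AGL6 by 2.32. UFO, an activator of AP3, fell by 5.04 (SE 0.39, adjusted p = 3.83e-06), from 4.91 ± 1.09 to 0.140 ± 0.111 CPM. AG, the stamen and carpel identity gene, was 1.93-fold higher (log2 fold change 0.95, SE 0.12, adjusted p = 0.000154). The carpel and ovule genes SHP1, SHP2 and STK were 5.95-fold, 4.16-fold and 9.79-fold higher, SUP was 2.55-fold higher and CRC 1.82-fold higher. Of 18 measured floral identity genes, 7 rose and 8 fell, 15 both over all genes and adjusted over the list alone, and with members going both ways the list did not pass as a whole (camera adjusted p = 0.962).

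Gynoecium and meristem genes changed as well. HEC1, HEC2 and HEC3, which act in carpel margins, rose by log2 fold changes of 1.44, 1.27 and 2.27, and STY1 (1.2), SPT (0.86) and ALC (0.53), regulators of the style and of carpel margin tissue, rose too. Of 10 measured carpel and ovule genes 5 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00319; adjusted p = 0.293 with an estimated correlation). INO, a gene of the outer ovule coat, had 0, 0, 0 and 1 counts in the WT libraries and 5, 14, 12 and 20 in those of ap2-12 (adjusted p = 0.00383), a ratio of 46.8 with an exact (Clopper-Pearson) 95% interval of 8.03 to 1880, which covers counting error only. STM, which keeps meristem cells undifferentiated, fell by 1.18 (SE 0.15, adjusted p = 0.000206) and ATH1 by 0.86, while WUS, the stem cell organiser gene, was at 6.67 ± 1.28 CPM in WT and 6.02 ± 0.891 CPM in ap2-12 (adjusted p = 0.629). Of 16 meristem and boundary genes 4 rose and 4 fell, or 5 and 4 adjusted over the list alone, and the list did not pass (adjusted p = 0.962).

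Photosynthesis genes and xylem genes were lower in ap2-12. Of 22 photosynthesis genes 18 fell and 0 rose, or 20 adjusted over the list alone (camera adjusted p = 3.02e-34; adjusted p = 0.0264 with an estimated correlation), with a median log2 fold change of -0.74. Carbonic anhydrase CA1 fell by 4.19 (SE 0.18, adjusted p = 3.3e-08), from 164 to 8.96 CPM. The small Rubisco subunit genes RBCS1B and RBCS2B fell by 3.39 and 3.54, RBCS3B by 1.51, and RBCS1A, the most abundant copy at 4448 CPM in WT, by 0.93. These RBCS copies are near-identical, so the split of reads among them is uncertain. Of 13 xylem and secondary wall genes 10 fell and 0 rose, or 12 adjusted over the list alone (camera adjusted p = 6.23e-16; adjusted p = 0.00243 with an estimated correlation). Among them, the protease gene XCP1 fell by 2.06, the cellulose synthase gene CESA4 by 1.52, and the laccase genes LAC4 and LAC17 by 1.6 and 1.5.

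Genes of the tapetum, the anther cell layer that feeds pollen, were higher in ap2-12. Of 18 measured tapetum and pollen genes 13 rose and 0 fell, or 14 adjusted over the list alone (camera adjusted p = 4.86e-07; adjusted p = 0.293 with an estimated correlation). QRT3 rose by 2.97 (SE 0.64, adjusted p = 0.00716), ATA20 by 2.84, CYP704B1 by 1.38 and PKSB by 1.24. The list mean also varied within genotypes, from -1.49 to 0.06 among WT libraries and from -0.26 to 1.58 among those of ap2-12 (log2 CPM, centred on all libraries).

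**Figure D3:**
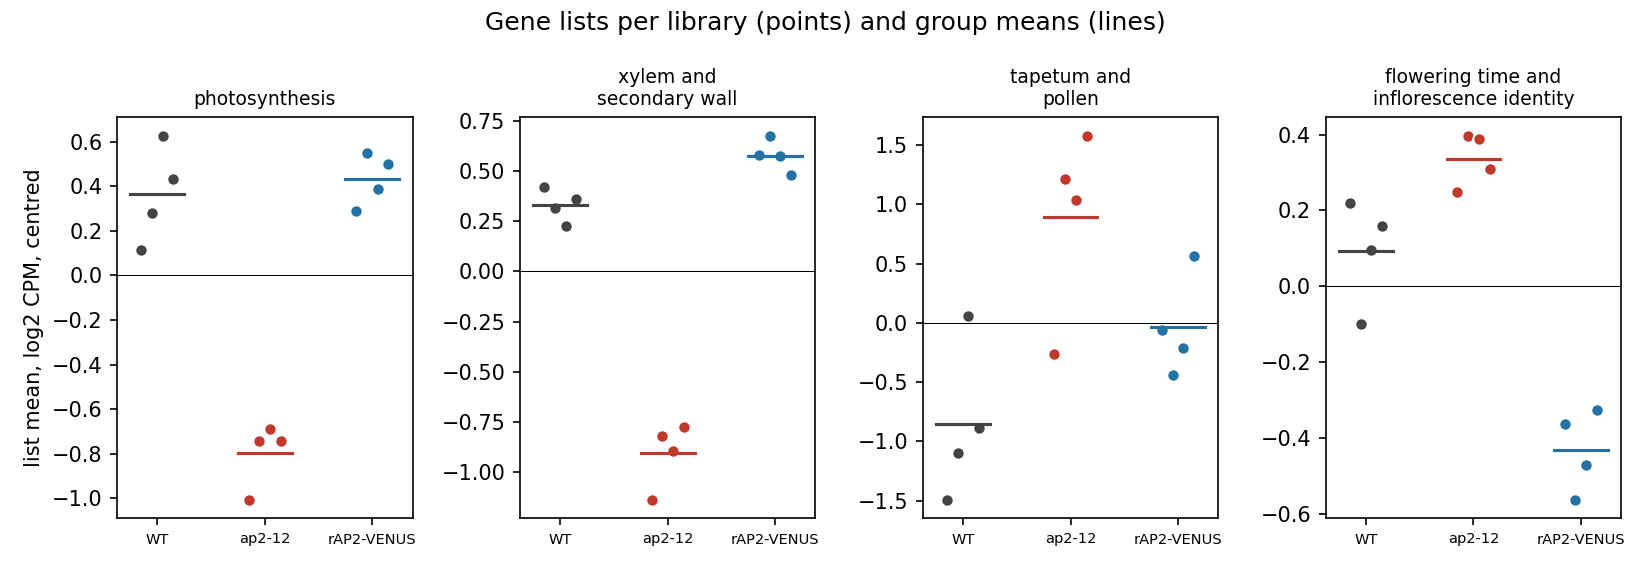
Mean log2 CPM of 4 gene lists per library, centred on the mean of all 12 libraries, with a point per library and a line at the group mean. For photosynthesis the ap2-12 libraries lie at -1.01 to -0.69 and all others above 0, for xylem at -1.14 to -0.77, and for flowering time those of rAP2-VENUS lie at -0.562 to -0.325.

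The largest changes in ap2-12 are given here for genes with a symbol, a mean of at least 5 CPM and no overlap between the groups. Among the decreases were the following. CSLA01, a mannan synthase gene, fell by 6.83 (SE 0.59, adjusted p = 8.87e-06), and RXF26 fell from 124 to 1.3 CPM (log2 fold change -6.59). The cytochrome P450 genes CYP86A7 and CYP86A4, whose family makes hydroxylated fatty acids for cutin, fell by 6.11 and 5.01, CA2 by 5.99, GLC by 5.08 and the proline-rich protein gene PRP4 went from 560 to 31.5 CPM (log2 fold change -4.15). The largest increases were in SCPL43 (log2 fold change 4.05, SE 0.28, adjusted p = 1.7e-06), FTM1 (3.49), STK (3.29), the homeobox gene ATHB54 (3.19), QRT3, ATA20, MPL1 (2.69) and SHP1.

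Flowering regulators went both ways in ap2-12. SOC1, a promoter of flowering, rose by a log2 fold change of 1.26 (SE 0.10, adjusted p = 7.25e-06), FUL by 0.61, AGL42 by 0.79 and the repressor SVP by 0.88, while TFL1, which keeps the inflorescence indeterminate, fell by 1.25. Of 10 measured flowering genes 4 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.0131; adjusted p = 0.288 with an estimated correlation). Of 5 measured miR172 targets, TOE1 (1.21) and SMZ (1.21, adjusted p = 0.0376) rose and AP2 fell, TOE3 was at 0.88 (adjusted p = 0.0914; 1.23 and 0.0148 without WT replicate 1), and the list did not pass (adjusted p = 0.349). That list includes AP2, the gene altered in this mutant, so its test does not speak for the other members alone. Adjusted over the list alone 3 rose and 1 fell. With the block edgeR called TOE3 over all genes (adjusted p = 0.000557). SMZ lost its call in 6 of 8 single-library omissions, with adjusted p up to 0.116. Of 9 miR156-targeted SPL genes, which promote floral transition, 4 fell on both adjustments. These were SPL4 (-0.63), SPL5 (-1.10), SPL9 (-0.71, adjusted p = 0.0507 without ap2-12 replicate 4) and SPL3 (-0.59, lost in 6 of 8 omissions, with adjusted p up to 0.109). That list had an adjusted p of 0.107, and 0.0485 without WT replicate 2.

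For auxin 3 of 16 genes rose, or 5 adjusted over the list alone, namely GH3.3 (1.31), YUC4 (1.22) and TAA1 (0.76) over all genes with ETT at 0.28 (adjusted p = 0.0583). ETT was called by edgeR with the block (adjusted p = 0.0093) and by DESeq2 (0.0178). The auxin list had a camera adjusted p = 0.0247 (adjusted p = 0.436 with an estimated correlation; 0.105 without WT replicate 3 and 0.066 without WT replicate 4). For gibberellin 3 of 19 rose and 4 fell, or 4 and 5 on the list alone, with GASA6 at -3.23, GA2OX1 at -1.05, GA2OX4 at 2.12 and GID1B at 0.52 (list adjusted p = 0.962). For abscisic acid 4 of 13 fell, HAI2 (-1.56), ABI2 (-1.2), ABI1 (-0.60) and NCED3 (-1.26), and on the list alone 4 fell and 1 rose (list adjusted p = 0.062; from 0.0176 to 0.0324 when WT replicate 1 or 2 or ap2-12 replicate 3 or 4 was left out). For cytokinin LOG4 rose (0.97; adjusted p = 0.0564 without ap2-12 replicate 2) and CKX1 fell (-1.49; 0.0502 without WT replicate 2 or without ap2-12 replicate 4), 2 of 17 on both adjustments (list adjusted p = 0.962). Not called by edgeR without the block were AHK4 at -0.42 (0.0952) and CKX7 at 0.26 (0.184). With the block AHK4 was called (adjusted p = 0.00182). For expansins and xyloglucan remodelling 2 of 13 rose and 4 fell, or 2 and 5 on the list alone, with EXPA3 at -0.76, EXPA8 at -2.95, XTH24 at -1.81 and XTH28 at 0.71 (list adjusted p = 0.171).

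Of 23 cell cycle genes, CYCD3;2 rose (0.42, adjusted p = 0.0311, lost in 5 of 8 omissions, with adjusted p up to 0.0938), and none passed over the list alone (list adjusted p = 0.483). KRP2 stood at -0.42 (0.086), CYCB1;3 at 0.29 (0.102) and CYCB2;3 at 0.25 (0.132). With the block, edgeR called KRP2 (adjusted p = 0.0214), CYCB1;3 (0.0418) and CYCB2;3 (0.0359). EDS1 (0.54, lost in 4 of 8 omissions, with adjusted p up to 0.0703) was the only gene of 8 called by edgeR without the block for salicylic acid and defence, against 5 adjusted over the list alone (camera adjusted p = 0.0352; adjusted p = 0.472 with an estimated correlation). NPR1 stood at 0.33 (0.0766), WRKY18 at 1.11 (0.0834) and SARD1 at 1.90 (0.0904). DESeq2 called NPR1 (adjusted p = 0.0404), WRKY18 (0.0259) and SARD1 (0.0251), and edgeR with the block called NPR1 (0.0416) and WRKY18 (0.0315). That list lost its call without WT replicate 3 (0.0986), WT replicate 4 (0.0594) or ap2-12 replicate 4 (0.107). For sample handling (heat, wounding and touch) and for the clock, edgeR without the block called 0 of 14 and 0 of 12 genes on both adjustments (list adjusted p = 0.341 and 0.588). With the block, edgeR called LOX3 (adjusted p = 0.039), HSP70 (0.0026), HSFA2 (0.0279), GI (0.046) and TOC1 (0.0424). DESeq2 called LOX3 (0.01) and HSP70 (0.0227). Without the block, the values nearest the threshold were those of LOX3 (1.13, adjusted p = 0.0529), HSP70 (0.66, 0.055), HSFA2 (-1.33, 0.158) and WRKY33 (1.57, 0.182) for handling. For the clock they were those of GI (0.28, 0.39), PRR7 (0.16, 0.443), TOC1 (0.37, 0.514) and LHY (-0.59, 0.677). The sign for LHY turned to 0.332 without WT replicate 1.

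In all, 2866 of 18807 genes were called between ap2-12 and WT, 1063 higher and 1803 lower, and 1010 of them changed at least 2-fold. A fit with the replicate number as a block called 5419 genes, 2421 higher and 2998 lower. The groups did not overlap for 18.6% of the genes, against 2.86% by chance. Apices in which organs or tissues differ in share give such differences without a change inside any cell type.

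The comparison of rAP2-VENUS with WT asks how this line differs from WT. With the single line #A6, effects of the construct, of its place in the genome and of the line's background cannot be told apart. Flowering genes fell. SOC1 fell by 1.1 (SE 0.11, adjusted p = 0.00038), from 50 ± 7.59 to 23.3 ± 1.92 CPM, FUL by 0.73 (adjusted p = 0.00542), AGL42 by 0.83 (0.022) and SVP by 0.71 (0.0352). These were the 4 called members of 10 measured flowering genes, 6 fell adjusted over the list alone, and the list was lower (camera adjusted p = 1.07e-14; adjusted p = 0.0026 with an estimated correlation). SVP lost its call in 7 of 8 single-library omissions (all but WT replicate 3, with adjusted p up to 0.113), and AGL42 without WT replicate 1, WT replicate 4 or rAP2-VENUS replicate 4 (up to 0.0699). Among miR172 targets, TOE1 stood at -1.21 (SE 0.25, adjusted p = 0.0512; 0.00185 with the replicate number as a block) and TOE3 at -1.45 (0.109; 0.00111 with the block), SMZ at -1.22 (0.385) and TOE2 at 0.14 (0.763). None was called over all genes by edgeR without the block, DESeq2 called TOE1 (adjusted p = 0.000483) and TOE3 (0.00382), and 3 fell over the list alone (camera adjusted p = 0.000414; adjusted p = 0.104 with an estimated correlation).

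Within the same limits of level and symbol, the largest increases in rAP2-VENUS were in MRD1 (log2 fold change 6.09, SE 0.21, adjusted p = 7.52e-09), from 0.571 ± 0.053 to 39.7 ± 5.32 CPM. AT3G01345, a gene without a symbol, chosen after its values were seen, rose from 0.533 ± 0.321 to 744 ± 150 CPM (10.37, SE 0.31, adjusted p = 2.34e-09). HEI10, a gene of meiotic crossover formation that adjoins MRD1, rose by 1.32. The myrosinase genes TGG1 and TGG2, whose enzymes cleave glucosinolates, rose 3.24-fold and 3.32-fold, to 2434 and 3290 CPM. They are related copies, so reads may be shared between them. GDU4 (1.42), SCPL43 (1.74), HIPP20 (1.23) and the gibberellin synthesis gene GA20OX2 (1.28) also rose. The largest decreases within these limits were in sks13 (-2.20), the transporter gene ABCB15 (-1.40), CYP97B3 (-1.25), PCK1, a gene of gluconeogenesis (-1.11), SOC1, CYP96A15 (-1.02), AAH (-0.98) and SRS7 (-0.95). Single-library omissions ended the calls of GA20OX2 in 7 of 8 cases (adjusted p up to 0.0849), SCPL43 in 6 (0.0811), CYP96A15 in 6 (0.165), sks13 in 3 (0.0734), HIPP20 in 3 (0.0617) and SRS7 in 2 (0.0617).

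Counts for the other lists in rAP2-VENUS are those of edgeR without the block. DESeq2 also called AP1 (adjusted p = 0.00315), CRC (0.0177), GA3OX1 (0.0221), LAC17 (0.00504), LAC4 (0.00431) and XCP1 (0.033). The floral identity list had 0 called of 18 (adjusted p = 0.812; 3 rose and 6 fell on the list alone), with AP1 at -0.29 (adjusted p = 0.102; 0.0281 with the block), AG at 0.05 (adjusted p = 0.991), SHP2 at 0.43 (0.129), CRC at -0.79 (0.14; 0.0103 with the block) and AGL6 at -0.56 (0.147; 0.0322 with the block). SPL10 fell by 0.60 (adjusted p = 0.0358, lost in 6 of 8 omissions with adjusted p up to 0.126), the only call among 9 SPL genes on both adjustments (list adjusted p = 0.127; 0.0393 with the block). SPL11 stood at -0.19 (0.757), SPL2 at -0.24 (0.855) and SPL15 at 0.19 (0.946). The xylem list stood higher with 0 called of 13, or 5 on the list alone (camera adjusted p = 6.42e-05; adjusted p = 0.0815 with an estimated correlation). LAC17 stood at 0.65 (0.0866; 0.0295 with the block), LAC4 at 0.64 (0.102; 0.0419 with the block), XCP1 at 0.70 (0.209) and XCP2 at 0.45 (0.311). The tapetum list stood higher with 0 of 18 called (camera adjusted p = 0.000458; adjusted p = 0.611 with an estimated correlation) and the cell cycle list lower with 0 of 23 (0.00328; adjusted p = 0.611 with an estimated correlation). ATA20 stood at 1.62 (0.461), QRT3 at 1.42 (0.616), MS1 at 1.62 (0.775) and ATA7 at 2.39 (0.801). Over the alternative fits and omissions, which called none of them, ATA20 ran from 0.887 to 2.094 and QRT3 from 0.909 to 2.353. MS1 ran from 1.158 to 3.353 and ATA7 from 0.941 to 7.836. CYCB2;2 stood at -0.26 (0.434), CYCD1;1 at -0.30 (0.444), CYCA1;1 at -0.25 (0.619) and CYCB2;4 at -0.18 (0.645). The clock list, 0 of 12 called, had an adjusted p of 0.257, and 0.0236 upwards with the block. GI stood at 0.38 (0.705), FKF1 at 1.60 (0.818; 0.0355 with the block), ELF4 at 1.55 (0.819) and TOC1 at 0.49 (0.859). GA20OX2 was the only call among 19 gibberellin genes (list adjusted p = 0.613), with 1 higher and 2 lower on the list alone. GA3OX1 stood at -1.86 (0.141), GA20OX1 at -1.12 (0.156) and GA2OX4 at -1.59 (0.374).

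With 0 genes called, adjusted p for the lists was 0.847 for meristem, 0.613 for auxin, 0.285 for cytokinin, 0.489 for abscisic acid, 0.812 for expansins, 0.678 for carpel, 0.3 for photosynthesis, 0.257 for handling and 0.954 for defence in rAP2-VENUS against WT. Adjusted over the list alone, 1 cytokinin gene and 1 abscisic acid gene were lower, 1 handling gene was higher, 1 carpel gene was higher and 2 were lower.

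Members of these lists with the smallest adjusted p, none of them called by edgeR without the block, were as follows in rAP2-VENUS against WT. DESeq2 called CKX7 (adjusted p = 0.0252), NCED3 (0.0246), NGA2 (0.0218) and VSP2 (0.0346). For meristem these were WUS (0.41, adjusted p = 0.518), HEC1 (-0.57, 0.539), HEC2 (-0.53, 0.689) and BLH9 (0.14, 0.793). For auxin they were IAA14 (-0.71, 0.578), GH3.5 (0.82, 0.581; 0.00454 with the block), TAA1 (0.31, 0.655) and ETT (0.11, 0.898), and for cytokinin CKX7 (-0.50, 0.12; 0.0427 with the block), ARR8 (-0.43, 0.355), CKX6 (-0.25, 0.898) and ARR9 (-0.22, 0.925). Abscisic acid genes were NCED3 (-1.40, 0.0723; 0.044 with the block), HB21 (-1.03, 0.507; 0.0141 with the block), HB53 (-0.95, 0.86) and RD26 (0.33, 0.947). Expansin and xyloglucan genes were XTH4 (0.25, 0.268), EXPA8 (-0.80, 0.418), XTH22 (2.14, 0.444) and XTH15 (0.64, 0.553; 0.00291 with the block). Carpel genes were NGA2 (-0.76, 0.0961), STY1 (-0.58, 0.311), STY2 (0.15, 0.933) and INO, with 2, 2, 1 and 12 counts (adjusted p = 0.277), a ratio to WT of 17.3 with an exact 95% interval of 2.71 to 723. Photosynthesis genes were CA1 (0.36, 0.553; 0.0203 with the block), RBCS2B (0.33, 0.665), RBCS3B (0.18, 0.701) and LHCB1.1 (0.17, 0.918). Handling genes were VSP2 (0.40, 0.174), HSFA2 (-1.65, 0.41), HSP70 (0.55, 0.459) and HSP18.2 (0.42, 0.459), and defence genes WRKY18 (0.67, 0.804), EDS1 (-0.20, 0.895), SID2 (-0.11, 0.946) and SARD1 (0.67, 0.947).

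In all, 118 genes were called between rAP2-VENUS and WT by edgeR, 49 higher and 69 lower, 74 of them at least 2-fold, and 1500 genes had an unadjusted p under 0.05. With the replicate number as a block the count was 424, 207 higher and 217 lower, and all 118 were among them. The count fell to 69 without WT replicate 1, 57 without WT replicate 2, 58 without WT replicate 4, and 76, 64, 55 and 71 without rAP2-VENUS replicates 1, 2, 3 and 4.

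Against WT, 44 genes were called in opposite directions in ap2-12 and rAP2-VENUS and 36 in the same direction. Among those lower in ap2-12 and higher in rAP2-VENUS (27 genes) were TGG2 (-1.37 and 1.73), TGG1 (-1.11 and 1.70), the amino acid transporter gene UMAMIT14 (-0.97 and 1.02), PPCK1 (-0.49 and 0.66), HIPP20 (-0.94 and 1.23) and GDU4 (-0.71 and 1.42). Among those higher in ap2-12 and lower in rAP2-VENUS (17 genes) were SOC1 (1.26 and -1.1), FUL (0.61 and -0.73), PCK1 (0.96 and -1.11), UMAMIT30 (1.27 and -2.58), ARF11 (0.39 and -0.57) and LPLAT2 (0.61 and -0.69). Independent lists of these sizes would share 8.6 genes in opposite and 9.38 in the same direction. With the WT libraries split 2 and 2 in all 6 ways the opposite count was 10 to 66 and the same-direction count 4 to 20, where independent lists would give 0.901 to 9.79 opposite genes.

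Across genes the log2 fold changes of both comparisons correlated at 0.309, against 0.502 in the simulations that share WT without effects, and their covariance was 0.0793 against 0.0328. The value of 0.502 follows from sharing WT between groups of equal size without changed genes. Genes changed in a single genotype lower the correlation, so a value under 0.502 does not show opposite changes. With WT split 2 and 2 the correlation was 0.033 to 0.292 and the covariance 0.0116 to 0.0956. Neither reference takes the replicate numbers into account, since the simulations hold no deviation shared by number and the splits of WT part the numbers unevenly (the 66 came with WT replicates 3 and 4 set against ap2-12). Genes are not independent replicates. The opposite count fell to 28 without WT replicate 1, 17 without WT replicate 2, 23 without WT replicate 4, 29 without ap2-12 replicate 2, and 28, 24, 23 and 29 without rAP2-VENUS replicates 1 to 4. The same-direction count fell to 20, 17 and 18 without WT replicates 1, 2 and 4, and to 18 and 22 without rAP2-VENUS replicates 3 and 4. With the replicate block 153 were opposite and 117 in the same direction. Among changes of at least 2-fold the balance turned, with 12 opposite and 26 in the same direction.

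**Figure D4:**
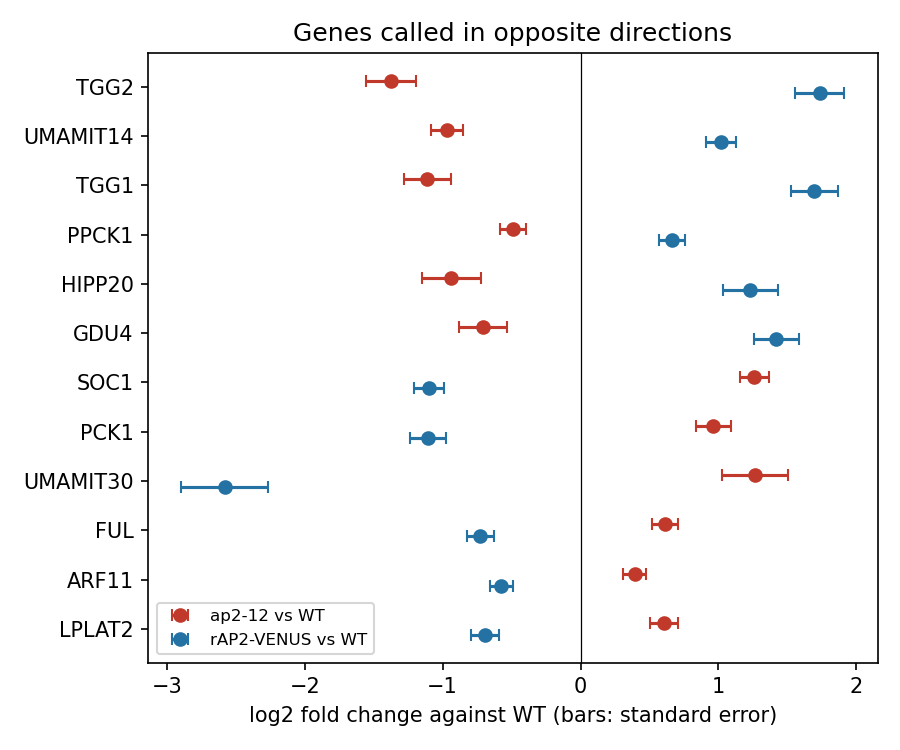
Log2 fold changes against WT, with standard errors, of the 12 named genes called in opposite directions in ap2-12 and rAP2-VENUS. UMAMIT30 spans the widest range, from 1.27 in ap2-12 to -2.58 in rAP2-VENUS, and ARF11 a narrow range, from 0.39 to -0.57.

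Set directly against each other, rAP2-VENUS and ap2-12 differed in 3686 genes, 2207 higher and 1479 lower in rAP2-VENUS, 1175 of them at least 2-fold. The fit with the replicate block called 6215 genes, 3436 higher and 2779 lower in rAP2-VENUS. AP2 was 2.73-fold higher (log2 fold change 1.45, SE 0.23, adjusted p = 0.000749). SOC1 was lower by a log2 fold change of -2.36 (SE 0.11, adjusted p = 4.12e-08), FUL by -1.34, AGL42 by -1.62, SVP by -1.59, TOE1 by -2.41, TOE3 by -2.33 and SMZ by -2.43. Of 10 flowering genes 5 were lower and 0 higher (camera adjusted p = 5.2e-09; adjusted p = 0.00956 with an estimated correlation), and 5 were lower and 1 higher adjusted over the list alone. Of 5 miR172 targets 3 were lower and AP2 was higher on both adjustments (camera adjusted p = 0.0221, and 0.292 with an estimated correlation). This list test also includes AP2, the gene altered in ap2-12. The largest differences among genes with a symbol, a mean of at least 5 CPM and no overlap were CSLA01 (6.88), CA2 (6.83), MRD1 (6.42), RXF26 (6.34) and CYP86A7 (5.91) upwards, and FTM1 (-5.17), ATHB54 (-3.30), PRN (-3.28), TOE1 and SHP1 (-2.36) downwards. TGG1 and TGG2 were 7-fold and 8.6-fold higher and GA20OX2 4.97-fold higher.

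In rAP2-VENUS against ap2-12, 18 of 22 photosynthesis genes were higher, or 20 adjusted over the list alone (camera adjusted p = 6.83e-30; adjusted p = 0.0261 with an estimated correlation), with CA1 at 4.55, RBCS1B at 3.49, RBCS2B at 3.87 and RBCS3B at 1.69. Of 13 xylem genes 10 were higher, or 11 on the list alone (camera adjusted p = 5.47e-20; adjusted p = 0.000974 with an estimated correlation), with XCP1 at 2.76, LAC4 at 2.24, LAC17 at 2.15 and CESA4 at 1.86. Of 18 floral identity genes 8 were higher and 8 lower on both adjustments, UFO at 5.57, AP1 at 0.85 and SHP2 at -1.63 among them (list adjusted p = 0.955). Carpel genes were lower in 4 of 10, or 1 higher and 5 lower on the list alone (camera adjusted p = 0.00357; adjusted p = 0.27 with an estimated correlation), with STY1 at -1.77, SPT at -0.76, NGA2 at -1.03 and ALC at -0.56. Tapetum genes were lower in 5 of 18, or 11 on the list alone (camera adjusted p = 0.00464; adjusted p = 0.539 with an estimated correlation), with CYP704B1 at -1.07, PKSB at -0.92 (adjusted p up to 0.0877), CYP703A2 at -1.91 (up to 0.117) and ABCG26 at -0.95 (up to 0.117), the last 3 lost in 6 of 8 omissions each. Cell cycle genes were lower in 6 of 23 and higher in 1, or 7 and 2 on the list alone, with CYCB2;3 at -0.45, CYCD3;2 at -0.50, CYCB1;3 at -0.42 and KRP2 at 0.66 (camera adjusted p = 0.0496; adjusted p = 0.573 with an estimated correlation). That list lost its call without ap2-12 replicate 1 (0.188) and without rAP2-VENUS replicate 3 (0.0983) or 4 (0.0644).

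The remaining lists did not pass between rAP2-VENUS and ap2-12. Counts and calls of genes in these lists are those of edgeR without the block. Higher and lower counts over all genes were 6 and 4 of 16 for meristem (STM at 1.18, ATH1 at 0.95, HEC3 at -2.29 and HEC1 at -2.01, adjusted p for the list 0.955), 4 and 4 of 19 for gibberellin (GASA6 at 3.15, GID1B at -0.80 and GA2OX4 at -3.71, list 0.955), 0 and 5 of 16 for auxin (GH3.3 at -1.42, YUC4 at -1.26, IAA14 at -0.98 and TAA1 at -0.46, list 0.0957). The calls of IAA14 and TAA1 were lost in 7 of 8 omissions each, with adjusted p up to 0.091 and 0.114. The counts were 0 and 2 of 17 for cytokinin (CKX7 at -0.76 and LOG4 at -1.07, with CKX1 at 1.14 and AHK4 at 0.45 not called, list 0.716) and 3 and 0 of 13 for abscisic acid (HAI2 at 1.47, ABI2 at 1.18 and ABI1 at 0.65, with ABF4 at -0.31 not called, list 0.262). They were 5 and 1 of 13 for expansins (EXPA3 at 0.60, EXPA8 at 2.15, XTH24 at 1.5 and XTH28 at -0.80, list 0.277) and 3 and 2 of 9 for SPL genes (SPL4 at 0.68, SPL5 at 1.06, SPL9 at 0.68, lost in 2 omissions with adjusted p up to 0.0524, and SPL10 at -0.67, list 0.613). They were 1 and 1 of 14 for handling (VSP2 at 0.44 and VSP1 at -0.47, the latter lost in 5 of 8 omissions with adjusted p up to 0.133, and LOX3 at -0.91 and HSP18.2 at 0.40 not called; list 0.916) and 0 and 1 of 8 for defence (EDS1 at -0.74, with NPR1 at -0.32, SARD1 at -1.23 and CBP60G at -1.40 not called; list 0.0658, and from 0.00858 to 0.0488 without ap2-12 replicate 1, 2 or 3 or rAP2-VENUS replicate 3). They were 0 and 0 of 12 for the clock (ELF4 at 1.68, FKF1 at 1.35, ELF3 at 0.14 and PRR9 at -0.32, list 0.955) and 0 and 2 of 4 for the neighbours of AP2 (SPT, and NAPRT1 at -0.22, lost in 6 of 8 omissions with adjusted p up to 0.108, with RAP2.10 at 0.59 and LEJ2 at -0.11 not called; list 0.35). Adjusted over the list alone, the counts were 8 and 5 for meristem, 4 and 6 for gibberellin, 1 and 5 for auxin, 4 and 2 for SPL genes, 1 and 0 for handling and 1 and 2 for the neighbours, with no change for the others. With the block, edgeR also called ELF4 (adjusted p = 0.00357), FKF1 (0.011), CKX1 (0.00635), AHK4 (0.000693), ABF4 (0.0207), NPR1 (0.0415) and RAP2.10 (0.0474). DESeq2 also called CKX1 (0.0194), AHK4 (0.0395), LOX3 (0.044) and NPR1 (0.0418).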

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

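The outlier check was a rule fixed in advance and ran on every gene named in the text. In 558 groups of 4 libraries (genes, gene lists and library totals), 32 had a highest or lowest library whose gap to its neighbour took more of the group's range than Dixon's critical value, where chance gives about 27.9. The gap share is given for each in brackets.

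Among WT libraries, replicate 1 was the highest for AP1 (0.863), CYCD1;1 (0.831), the miR172 target list (0.852) and the SPL list (0.933), and replicate 2 was the lowest for GA2OX1 (0.892). Replicate 3 was the highest for the tapetum genes ATA7 (0.899) and CYP703A2 (0.887). Replicate 4 was the lowest for ALC (0.867) and NGA2 (0.868) and the highest for XTH28 (0.836), XCP2 (0.868) and INO (1), whose only WT count it holds.

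Among ap2-12 libraries, replicate 1 was the lowest for RBCS2B (0.879), RBCS3B (0.882), UMAMIT14 (0.896), RD26 (0.866), ATA7 (0.843) and ABCG26 (0.841) and the highest for XTH24 (0.888). Replicate 4 was the highest for LOX3 (0.873) and the defence list (0.869).

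Among rAP2-VENUS libraries, replicate 1 was the lowest for HEC1 (0.94), KRP2 (0.849) and HB53 (0.887), and replicate 2 was the lowest for ABI2 (0.886) and the highest for TGG2 (0.921). Replicate 3 was the highest for UFO (0.947) and the lowest for RAP2.10 (0.885) and NGA2 (0.933). Replicate 4 was the lowest for TOE1 (0.905) and UMAMIT45 (0.838) and the highest for INO (0.853).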

How the results depend on the processing

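The replicate block, scalings, DESeq2, limma-voom, filters, thresholds and single omissions were chosen before the data were examined; leaving out the libraries numbered 1, with or without the block, and the clock score covariate were chosen after. For ap2-12 vs WT, rAP2-VENUS vs WT, rAP2-VENUS vs ap2-12 and the opposite directions, in this order, the 2866, 118, 3686 and 44 calls became 5419, 424, 6215 and 153 with the replicate block, 1010, 74, 1175 and 12 at 2-fold or more, 1465, 42, 2113 and 15 at an adjusted p under 0.01, and 5550, 574, 7677 and 228 with the clock score as a covariate. DESeq2 gave 340 for rAP2-VENUS vs WT and 115 opposite. Single omissions gave 2038 to 3143, 55 to 108, 2792 to 3723 and 17 to 56. Without the libraries numbered 1 rAP2-VENUS vs WT had 54 calls and 20 were opposite, and with the block as well 156 and 54. Thresholds give fewer calls by construction, and omissions leave fewer libraries yet some gave more calls. The block removes spread that libraries of a number share. For DESeq2 and for the covariate, whose score also differs between genotypes within a number, the cause was not tested. All 118 calls were among those of the block, the covariate and DESeq2.

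For ap2-12 vs WT and rAP2-VENUS vs ap2-12 the numbers were not taken to pair the samples, since not every pair's correlation was over 0.1, though libraries of a number share structure. The cutoff turned on replicate 2 in the former and on replicates 2 and 3 in the latter. It does not show that these libraries are unpaired. Correlations of deviations were 0.60, -0.01, 0.47 and 0.39, and 0.54, 0.06, 0.05 and 0.56, and 7 of 12 libraries correlated best with their own number in another genotype. The block ended the call of the defence list (adjusted p = 0.0593) and added that of the SPL list (0.0226) in ap2-12, and for named genes it added 13 calls in ap2-12 vs WT and 7 in rAP2-VENUS vs ap2-12 and ended 0. For rAP2-VENUS vs WT it changed no call beyond those in the report.

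Sign changes were confined to results that were not called, and their cause was not tested. AP2 in rAP2-VENUS against WT ran from -0.405 to 0.042 over single omissions (positive without WT replicate 1), AG from -0.03 to 0.116 (negative without WT replicate 3 and, at -0.009, without rAP2-VENUS replicate 1), and LEJ2 from -0.004 to 0.11. LHY in ap2-12 against WT ran from -1.334 to 0.332. With the clock score as a covariate LHY was at 0.003 there, and in rAP2-VENUS against WT SPT was at -0.026 and LEJ2 at -0.018.

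Of 5674 alternative values of 299 named gene results (AP2 apart, with its 1 reversal above), 5371 kept direction and side of the threshold, 160 lost and 136 gained a call and 7 reversed. In some single omission 8 of 93 named calls were lost in ap2-12 vs WT, 9 of 28 in rAP2-VENUS vs WT and 8 of 71 in rAP2-VENUS vs ap2-12. Of 684 values for lists, 643 kept them, 23 lost and 18 gained a call, and 13 of those lost were with the estimated correlation. Single omissions gave a call in rAP2-VENUS vs WT to the SPL list (adjusted p = 0.0409 without WT replicate 2 and 0.0277 without rAP2-VENUS replicate 1), cytokinin (0.0186 without WT replicate 4), photosynthesis (0.0124 without WT replicate 3) and handling (0.0409 without WT replicate 2 and 0.0175 without rAP2-VENUS replicate 4). No scaling moved the share of higher calls by over 10 points. For genes above the minimum mean count of the simulations, 1.5-fold changes were recovered in 49.3% of cases for ap2-12 vs WT and 55.2% for rAP2-VENUS vs WT.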

Other observations

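The gene family tests below, the clock score and the tests on photosynthesis genes, on AP2 dose and on other groupings by gene count, and the limit to groupings that part the pairs, were chosen after the results were seen; the tests on depth, harvest time, bud stage, neighbouring genes, methylation markers and groupings by list count had their predictions written first.

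Gene families by symbol gave further groups. For each of 121 families with at least 10 tested members, calls were compared with all other genes that have a symbol by one-sided Fisher's exact tests (242 tests per comparison). In ap2-12, PTAC genes, named for the plastid transcription complex, fell in 9 of 14 members, or 64.3% against 12.3% of other genes (adjusted p = 0.00182), with PTAC16 at -1.09 and PTAC5 at -0.61. UMAMIT genes, a family of amino acid transporters, fell in 12 of 28 and rose in 2 (adjusted p = 0.0068 and 1), with UMAMIT45 at -1.84 and UMAMIT47 at -1.57. Of 37 WRKY genes 8 rose (adjusted p = 0.0467) and 5 fell (adjusted p = 1). EMB genes, named for embryo defects, fell in 36 of 158 and rose in 3 (adjusted p = 0.0144 and 1), and PDE genes, named for pigment defects, in 7 of 15 (adjusted p = 0.0467).

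In rAP2-VENUS, UMAMIT genes rose in 3 of 28 (adjusted p = 0.0157), namely UMAMIT14, UMAMIT12 (2.18) and UMAMIT28 (2.95), and fell in 1, UMAMIT30. In ap2-12, UMAMIT14 fell, and UMAMIT12 (-0.19, adjusted p = 0.735) and UMAMIT28 (-1.08, adjusted p = 0.254) were not called. Members of a family are not independent of each other.

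Libraries with the same replicate number deviated together, and 5548 genes, 29.5% of those tested, differed between numbers. A difference in depth is argued against, since 88.6% of these genes were called again after every library was thinned to the smallest library total, 9680133 counts. All 12 clock genes differed between numbers, against 29.5% of all genes (two-sided Fisher's exact p = 4.31e-07), with mean log2 CPM of LHY at 7.15, 5.93, 4.93 and 4.2 and of FKF1 at 0.85, 2.33, 3.97 and 4.93 for numbers 1 to 4 (n = 3 each), so a candidate explanation is that apices of different numbers were taken at different hours. For the stage of the buds, 7 of 18 tapetum genes differed (two-sided Fisher's exact p = 0.438), which leaves it open, and 7 of 9 SPL genes and 13 of 22 photosynthesis genes differed too (adjusted p = 0.0261 each), which stage or tissue may give as well as the hour. A harvest day or a library batch cannot be tested, as the labels give neither, and no explanation beyond depth, harvest hour and bud stage was tested.

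Whether the genotypes differ in clock phase stays open, and an effect of genotype on clock genes would give the same score as another hour. A score of 6 evening minus 4 morning clock genes (mean log2 CPM) ran from -2.95 in WT replicate 1 to 3.04 in rAP2-VENUS replicate 4. Between rAP2-VENUS and WT of the same number it differed by 1.59, 2.53, -0.35 and 1.64 (exact sign-flip permutation p = 0.25, two-sided). For libraries not taken as paired, the same-number differences were 0.63, 1.58, -0.82 and 0.37 between ap2-12 and WT (exact p = 0.5), and 0.96, 0.94, 0.48 and 1.27 between rAP2-VENUS and ap2-12 (exact p = 0.125, the smallest that 4 differences allow).

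MRD1, HEI10 and AT3G01345 were higher in all 4 rAP2-VENUS libraries, with 410 to 662 counts of MRD1 against 5 to 9 in WT and 7792 to 12576 counts of AT3G01345 against 3 to 13. An extra copy of a wider segment that takes in the neighbours of MRD1 and HEI10 is argued against. The 10 nearest tested genes had a median log2 fold change of -0.044 (from -0.402 to 0.13, none called by edgeR). A copy of MRD1 and HEI10 alone would leave these neighbours unchanged, so their values do not bear on it. Loss of DNA methylation at many loci stays open. Of 3 genes known to be silenced by methylation, QQS stood at 1.021 (SE 0.568, adjusted p = 0.76), SDC at -0.406 (SE 0.492), and FWA had 7 counts in all libraries and was not tested. A response to AP2 dose may apply too, but in ap2-12 MRD1 was at -0.338 (adjusted p = 0.601), AT3G01345 at 0.53 (adjusted p = 0.435) and HEI10 at 0.46 (adjusted p = 0.0272, lost in 5 of 8 single omissions with adjusted p up to 0.0909), which does not decide it. A local change of sequence or chromatin in this line, at or apart from the construct, was not tested.

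Photosynthesis genes fell unevenly in ap2-12, from -0.287 to -4.19 on the log2 scale. Reads moving between the near-identical RBCS copies are argued against as the cause of the fall, because their summed CPM went from 5499 ± 639 in WT to 2627 ± 292 in ap2-12 (log2 ratio -1.066), with no overlap between the libraries. An even loss of green tissue that lowers each gene alike is also argued against, since Cochran's Q over the 22 members was 963 on 21 degrees of freedom. The genotype stays open as a cause. A loss of organs or cells that express CA1, RBCS1B and RBCS2B above the other members may give this pattern and was not tested.

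Other groupings of the 8 libraries of each comparison (35 with the real one) bear on chance. For ap2-12 vs WT 1 of 35 gave as many as 2866 genes, the next highest giving 885, and for rAP2-VENUS vs ap2-12 1 of 35 gave 3686, the next 9. The real grouping thus gave the most genes in both. These shares would exclude chance only if libraries were exchangeable. Libraries of a number share structure, so chance is not excluded by these shares alone. For rAP2-VENUS vs WT, where the numbers pair the libraries, 8 groupings part all 4 pairs, too few for a share under 0.05. The real one, 1 of 8, gave 118 genes and the highest other 0. With the block 1 of 8 gave as many as the real 424, the highest other giving 323 with replicate 3 exchanged between the genotypes. Groupings that keep pairs together differ in that they can follow the numbers. Over all 35, 2 gave 118 genes or more, the other being replicates 1 and 2 of both genotypes against replicates 3 and 4 with 3846 genes, which points to the structure of the samples by number.

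For gene lists at the preset correlation, 9 of 35 groupings gave at least the real 7 lists for ap2-12 vs WT (up to 12) and 2 of 35 at least 7 for rAP2-VENUS vs ap2-12 (up to 7), so chance cannot be excluded for these counts. With the estimated correlation the real grouping alone, 1 of 35, reached its 2 and 3 lists, the highest other giving 0 and 1. As libraries of a number share structure, these shares alone do not exclude chance either. For rAP2-VENUS vs WT 6 of the 8 groupings that part the pairs gave at least the real 5 lists (up to 9; 21 of all 35), and 1 of 8 the real 1 list with the estimated correlation (the highest other 0), again too few for a share under 0.05.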
